A study of Mus musculus with 18 samples.

How the data were processed

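RNA was sequenced from hearts of wild-type C57BL/6 mouse embryos at 5 stages, with 3 libraries at E9.5, 4 at E10.5, 4 at E12.5, 3 at E14.5 and 4 at E16.5. Per the labels' protocols, total RNA was extracted from dissected hearts and made into libraries by standard Illumina methods. The authors deposited whole-number counts of reads per gene for each of the 18 libraries, not normalized, keyed by Ensembl gene identifier. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 and the mouse builds GRCm38 and mm10. The order and role of these tools, the strand setting of the counting and the annotation release are not given in the sources used here. Without a strand setting, reads of antisense or overlapping genes may be counted for their partner, and reads shared between near-identical genes, such as the adult globins Hba-a1 with Hba-a2 and Hbb-bs with Hbb-bt or ribosomal proteins with their pseudogenes, may be split or lost, so such genes are uncertain.

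Library totals ran from 30744015 to 45646538 counts, and a count of 0 in a library allows a level of up to 3 counts of its total, which is 0.0657 to 0.0976 CPM. Of the 49315 identifiers, 48970 had a symbol and 49056 were found in the GENCODE M21 annotation of GRCm38, from which coordinates, types, exon lengths and GC content were taken. Identifiers without a symbol held 0.0238 to 0.0388% of the counts. Before replicates were averaged, each pair of libraries of a stage was compared by a chi-square test over genes with at least 10 counts per pair, and all 24 pairs differed by more than sampling noise (chi-square per degree of freedom 6.06 to 79.8).

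Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by stage, which left 18885, libraries were scaled with TMM, and 1 quasi-likelihood model (robust, with stage as the only term) was fitted to all 18 libraries, so that the stages share an estimate of the spread. The comparisons were E10.5 with E9.5, E12.5 with E10.5, E14.5 with E12.5, E16.5 with E14.5 and E16.5 with E9.5. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM of genes use TMM-scaled library sizes. The CPM of the 8 macrophage-type transcripts, of Gh, Pomc, Afp, Sftpc and Krt5, of Xist and of Y-linked genes use plain library totals. Principal components were taken from log2 CPM (prior count 2) of the 2000 most variable genes. Tests by exact permutation were two-sided.

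In all, 39 gene lists, 23 of pathways and 16 of cell types, were fixed before the data were examined, as were the model, the rule for named genes and most alternatives. They cover mevalonate pathway, cholesterol branch, protein prenylation, SREBP and sterol uptake, DNA replication, mitosis, cell cycle inhibitor, core sarcomere, early contractile isoform, calcium handling, fatty acid oxidation, citric acid cycle, nuclear respiratory chain, mitochondrially encoded, glycolysis, extracellular matrix, second heart field, cardiac transcription factor, LIN28 and oncofetal, trabecular and secreted factor, cytosolic ribosome, ribosome biogenesis, insulin-like growth and imprinted, primitive erythroid, adult globin, macrophage, megakaryocyte, endothelial, coronary endothelial, endocardial and valve, epicardial, fibroblast, mural cell, neural crest and Schwann cell, neuronal, endoderm and liver, lung epithelium and pharyngeal arch genes, and genes of the thymus and lymphoid cells, which had too few measured members to be tested. The other 38 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Per comparison, genes were named from the 8 largest rises and 8 largest falls (10 each for E16.5 with E9.5) among genes past the threshold with a mean of at least 10 CPM in the higher stage and no overlap between the libraries of the stages. Mitochondrial, ribosomal protein, haemoglobin, predicted, RIKEN-named and non-coding genes were left out there. Named too were the 3 members with the smallest p of each called list, in the direction of the list, and the mevalonate enzymes. Some named genes and called lists are not reported here, and tests of a list used all its members.

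On counts simulated from the means and library sizes of these libraries, with 50 genes changed at each fold among 18885, the shares recovered at folds of 1.5, 2, 4 and 8 were 46, 66, 92 and 98% for E10.5 with E9.5 and 60, 62, 86 and 98% for E12.5 with E10.5. They were 44, 60, 90 and 98% for E14.5 with E12.5, 40, 78, 78 and 90% for E16.5 with E14.5, and 40, 52, 96 and 96% for E16.5 with E9.5. False calls were 2.58, 1.29, 2.67, 4.03 and 4.70% of all calls in these comparisons.

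Alternatives were RLE size factors, library totals only, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the stages compared, a replicate block, replicates 1 to 3 only, libraries thinned to the smallest, mitochondrial and globin genes left out, an adjusted p under 0.01, a fold of at least 2, camera with an estimated correlation, fry, and leaving out each library in turn. The batches were found in the data, at a sum of 10 CPM of the 8 transcripts. A batch term, fits within batch 2 and within batch 1, and a fit without batch genes were chosen after seeing the data. Values within a batch come from fits to its libraries alone over the same 18885 genes. DESeq2 gave no adjusted p for 739 genes in E10.5 with E9.5 and 6 in each other comparison, and these stayed missing.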

Results

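Transcript abundance was measured by RNA sequencing of hearts dissected from wild-type mouse embryos of the inbred strain C57BL/6 at 5 stages, named by embryonic day as E9.5 and E10.5, then E12.5 and E14.5, and last E16.5. There were 3 libraries at E9.5, 4 at E10.5, 4 at E12.5, 3 at E14.5 and 4 at E16.5, 18 in all, and the labels give each as a pool of both sexes. Total counts per library ran from 30950152 to 32968212 at E9.5, from 37060489 to 44802875 at E10.5, from 36361812 to 45646538 at E12.5, from 30744015 to 42298365 at E14.5 and from 32550626 to 34109851 at E16.5. The title of the series names cardiac development, the mevalonate pathway and division of heart muscle cells. The comparisons of neighbouring stages and of the last with the first stage ask which transcripts changed in abundance between those days, and how the enzymes of the mevalonate pathway and genes of the cell cycle moved. The labels do not say that the libraries of a stage came from separate litters, so p-values measure the spread between these libraries, which may in part be technical. List sizes count the members tested, levels are means ± SD in CPM, log2 fold changes of genes are given ± SE, and floors and intervals cover counting error only.

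The first principal component of the 2000 most variable genes held 68.0% of their variance and ordered the stages, from -78.9 ± 33.9 at E9.5 over -52.6 ± 24.4 at E10.5, 7.51 ± 17.7 at E12.5 and 46.1 ± 5.49 at E14.5 to 69.7 ± 2.02 at E16.5. The second held 11.6% and set 5 libraries, replicates 2 and 3 of E9.5, 1 and 2 of E10.5 and 4 of E12.5, apart from the others of their stages. They also lay lower on the first component, at -94.6 and -102 against -40.0 for replicate 1 of E9.5. These 5 libraries, called batch 1 here, had a summed level of 0.582 to 2.75 CPM for 8 transcripts typical of activated macrophages and dendritic cells (Chil3, Mmp12, Mmp13, Gpnmb, Itgax, Cd74, H2-Aa and Atp6v0d2), against 341 to 689 CPM in the other 13, called batch 2. Batch 1 holds 2 of 3 libraries at E9.5, 2 of 4 at E10.5, 1 of 4 at E12.5 and none at the later stages, so batch and stage overlap in part, and fold changes within batches are given beside those over all libraries. Within batch 2 E9.5 has 1 library and within batch 1 E12.5 has 1, so p-values and counts there assume that a lone library varies like those of the other stages. With the batch as a term beside the stage, 4112 genes differed between batches (edgeR), 2198 of them higher in batch 2, and 486 were at least 4-fold higher there against 1 at least 4-fold lower. The share of counts from mitochondrial genes was 2.20 ± 0.168% at E9.5, 2.77 ± 0.334% at E10.5, 3.51 ± 0.237% at E12.5, 4.34 ± 0.536% at E14.5 and 5.56 ± 0.740% at E16.5. Globin transcripts, from the blood in the hearts, took 0.647 ± 0.147%, 1.19 ± 0.331%, 3.52 ± 1.47%, 1.04 ± 0.554% and 1.503 ± 0.519% at the same stages.

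**Figure D1:**
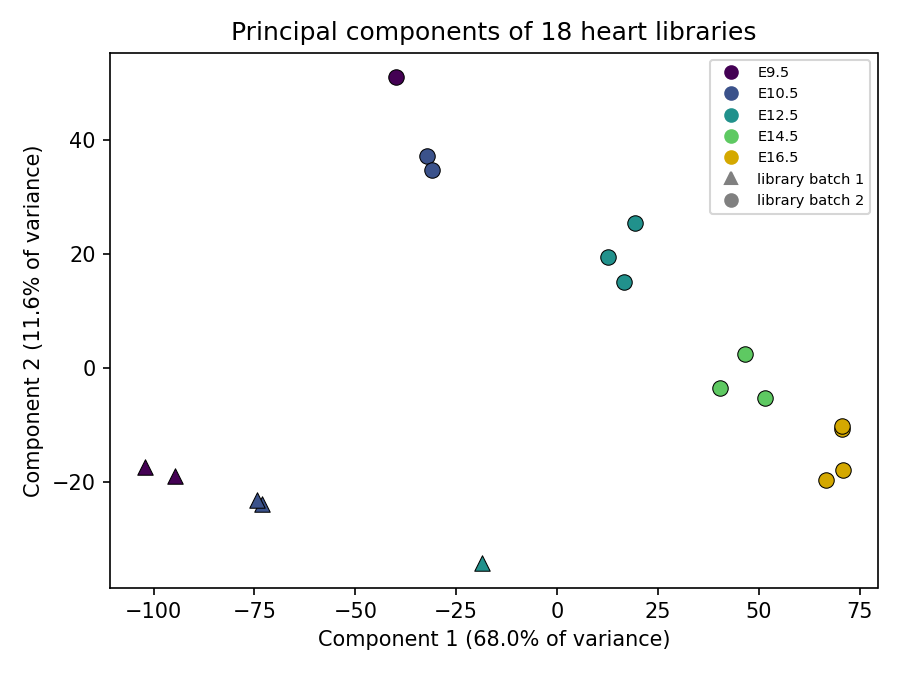
Principal component 1 (68.0% of the variance, horizontal) against component 2 (11.6%, vertical) for the 18 libraries, coloured by stage, with triangles for the 5 libraries of batch 1 and circles for the 13 of batch 2. The stage means follow each other along the first component, and the batches part along both components within E9.5 to E12.5.

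**Figure D2:**
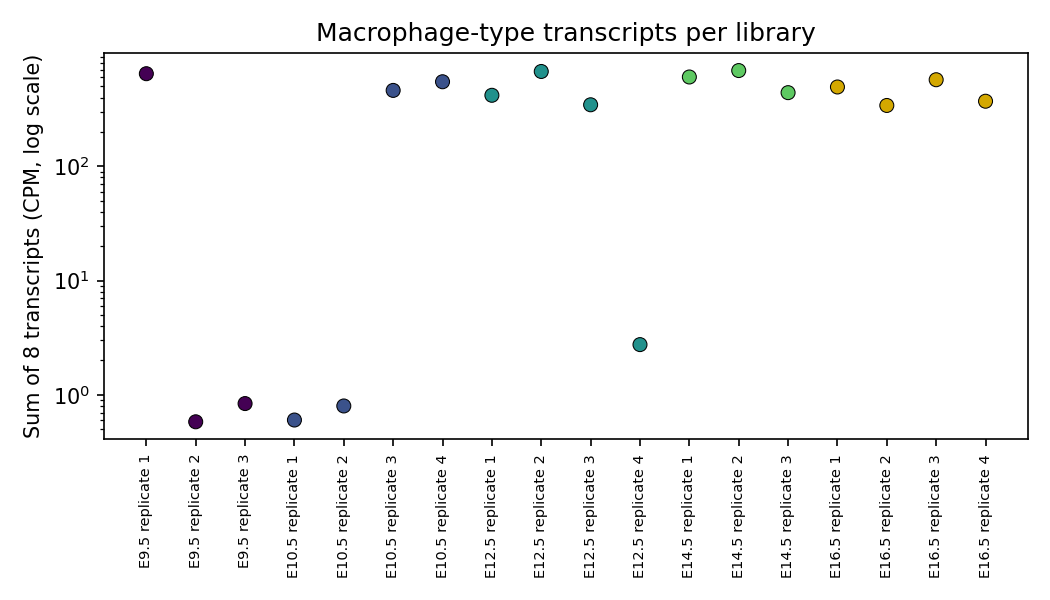
Summed level in CPM (log scale) of the 8 macrophage-type transcripts in each of the 18 libraries, coloured by stage. In 13 libraries the sum lies between 341 and 689 CPM and in 5 between 0.582 and 2.75 CPM.

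The mevalonate pathway makes the isoprenoid precursors of cholesterol and of protein prenyl groups from acetyl-CoA. The enzymes reported here, with coordinates in the mouse assembly GRCm38, were Acat2 (ENSMUSG00000023832, chromosome 17 from 12942890 to 12960747), Hmgcs1 (ENSMUSG00000093930, chromosome 13 from 119690379 to 119708260), Mvk (ENSMUSG00000041939, chromosome 5 from 114444269 to 114460591), Pmvk (ENSMUSG00000027952, chromosome 3 from 89454541 to 89469013), Mvd (ENSMUSG00000006517, chromosome 8 from 122433601 to 122443422), Idi1 (ENSMUSG00000058258, chromosome 13 from 8885501 to 8892451), Fdps (ENSMUSG00000059743, chromosome 3 from 89093588 to 89101959) and Ggps1 (ENSMUSG00000021302, chromosome 13 from 14050659 to 14063488). Exons of Hmgcs1 overlap the antisense gene Gm48342 over 12.1% of their length, those of Idi1 the opposite-strand gene Gm48574 over 9.21%, those of Fdps the same-strand gene Gm43738 over 26.7% and those of Ggps1 the opposite-strand gene Arid4b over 5.44%, so counts of these 4 are less certain. Their levels at E9.5 ran from 28.5 ± 2.49 CPM for Pmvk to 195 ± 12.496 CPM for Hmgcs1.

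**Figure D3:**
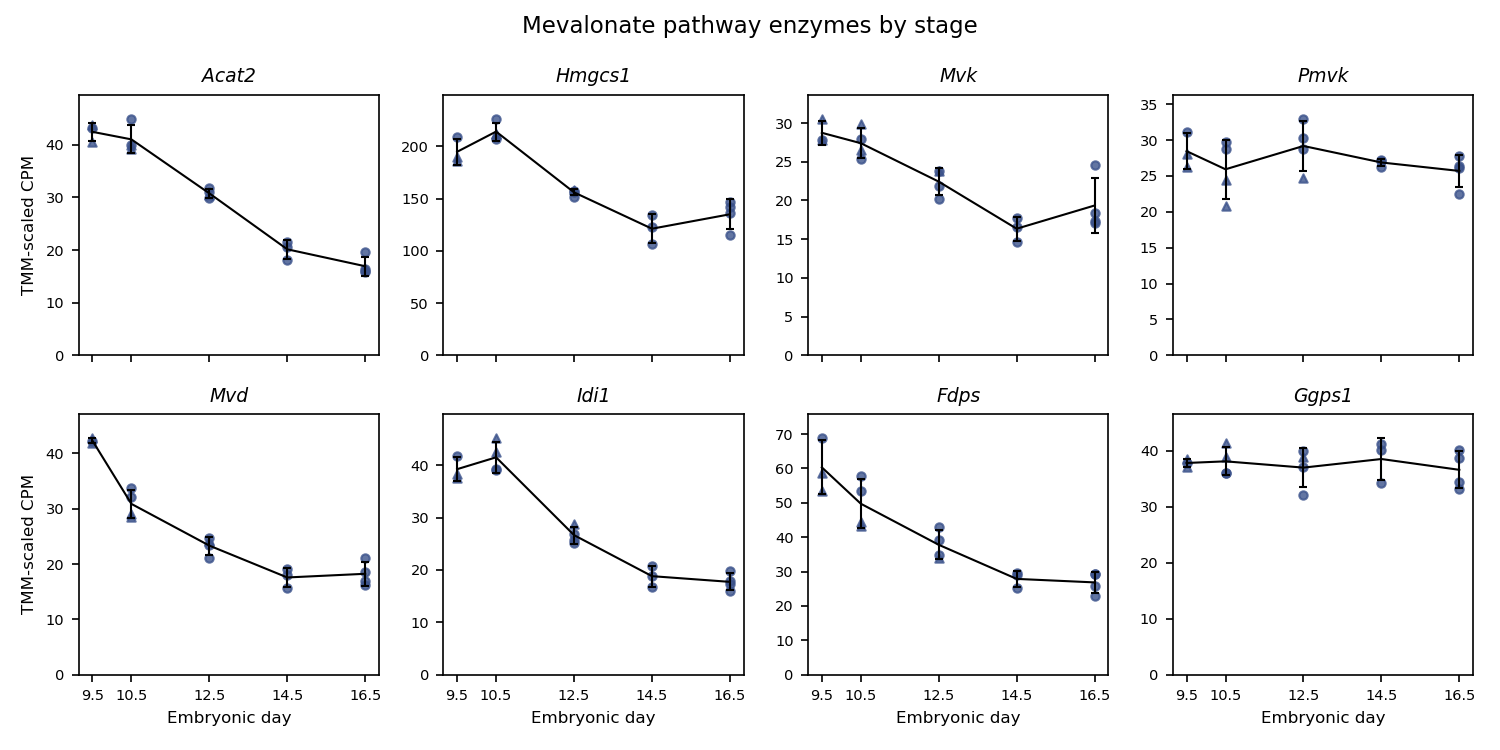
Level in TMM-scaled CPM (vertical) of 8 mevalonate pathway enzymes at the 5 stages (embryonic day, horizontal), with a point per library (triangles batch 1, circles batch 2) and the mean ± SD per stage. Idi1 had a mean of 39.3 CPM at E9.5 and 17.7 CPM at E16.5, and Ggps1 37.8 and 36.6 CPM.

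**Figure D4:**
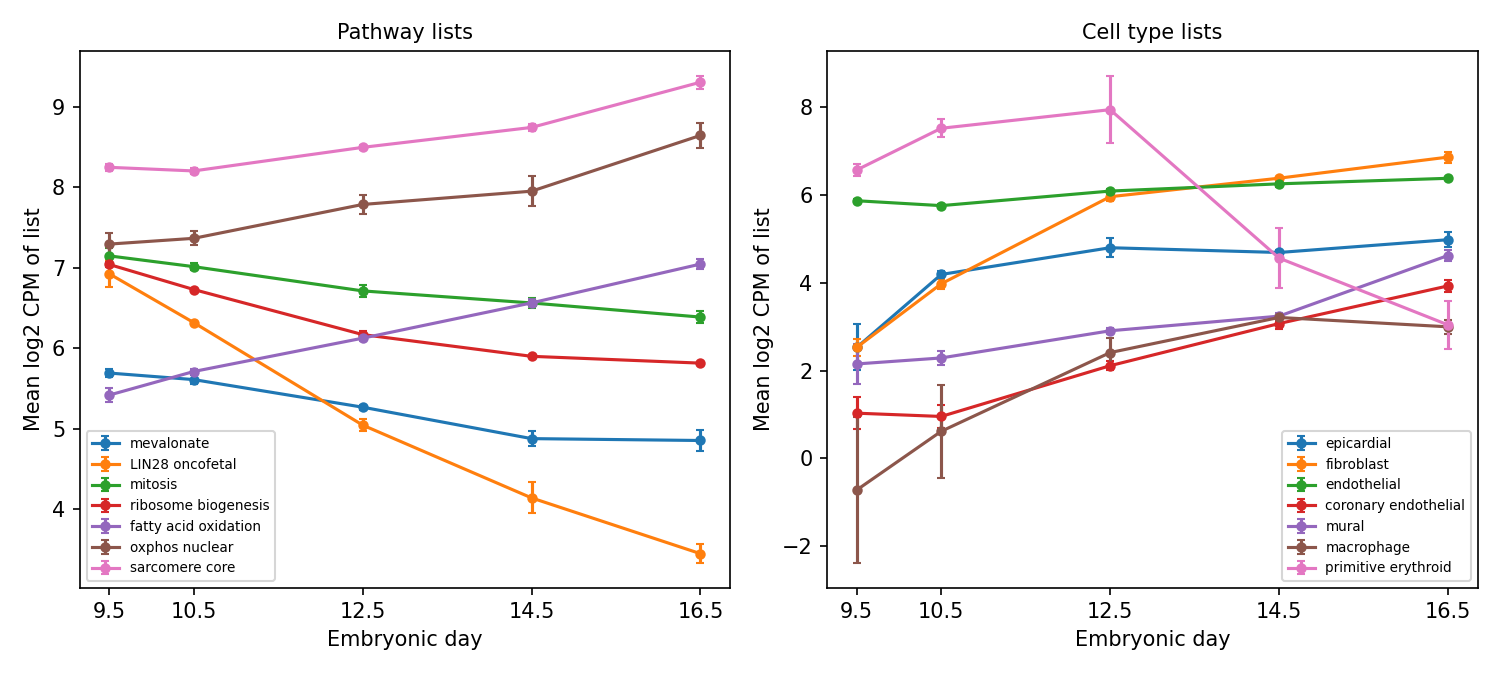
Mean log2 CPM over the members of 7 pathway lists (left) and 7 cell type lists (right) by embryonic day, as the mean ± SD of the libraries of each stage. LIN28 and oncofetal genes went from 6.93 ± 0.168 at E9.5 to 3.45 ± 0.119 at E16.5, and fibroblast genes from 2.53 ± 0.195 to 6.86 ± 0.126.

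Between E9.5 (n = 3) and E10.5 (n = 4), 10 of 13 fibroblast genes, 9 of 12 epicardial genes and 8 of 12 cell cycle inhibitor genes rose, while 18 of 22 ribosome biogenesis genes and 9 of 15 early contractile isoform genes fell, and these lists passed with camera at either correlation. Among the genes with the largest changes, Krt7, an epithelial keratin, rose from 1.43 ± 0.872 to 24.4 ± 4.70 CPM (log2 fold change 4.08 ± 0.309, edgeR adjusted p = 3.29e-07, with 4.52 in batch 1 and 3.50 in batch 2). Aldh1a2, which makes retinoic acid in the epicardium, rose from 3.71 ± 1.13 to 28.3 ± 5.23 CPM (log2 fold change 2.92 ± 0.195, edgeR adjusted p = 3.21e-08, with 3.31 in batch 1 and 2.41 in batch 2). The RNA-binding protein gene Lin28a, which holds back let-7 microRNAs in early embryos, fell from 140.1 ± 44.1 to 17.5 ± 3.63 CPM (log2 fold change -3.00 ± 0.259, edgeR adjusted p = 1.56e-06, with -3.40 in batch 1 and -2.43 in batch 2), and Foxh1, a transcription factor of Nodal signalling, from 31.8 ± 14.1 to 4.24 ± 1.04 CPM (log2 fold change -2.91 ± 0.292, edgeR adjusted p = 2.29e-06, with -3.41 in batch 1 and -2.13 in batch 2). The matrix gene Fmod (2.26 ± 0.945 to 16.495 ± 3.28 CPM, 3.06 in batch 1 and 2.67 in batch 2) rose as well. The retinoic acid-binding protein gene Crabp2 (19.5 ± 2.69 to 3.03 ± 1.34 CPM, -3.36 in batch 1 and -2.12 in batch 2) and the secreted Wnt antagonist gene Sfrp5 (38.4 ± 11.1 to 11.3 ± 2.83 CPM, -2.20 in batch 1 and -1.02 in batch 2) fell.

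Of 13 fibroblast genes, 10 rose and 3 did not pass, and 11 rose adjusted over the list alone. Fibroblast genes had a median of 1.57 (1.69 in batch 1 and 1.35 in batch 2) at a camera adjusted p of 8.2e-23 (adjusted p = 0.000653 with an estimated correlation). The collagen gene Col3a1 (125 ± 22.0 to 361 ± 24.7 CPM, 1.69 in batch 1 and 1.33 in batch 2) is an example. Of 12 epicardial genes, 9 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. A median of 1.86 (2.05 in batch 1 and 1.59 in batch 2) went with a camera adjusted p of 6.49e-17 (adjusted p = 0.00544 with an estimated correlation). Of 39 extracellular matrix genes, 21 rose, 4 fell and 14 did not pass, and 26 rose and 4 fell adjusted over the list alone. Their median was 0.56 (0.53 in batch 1 and 0.69 in batch 2), with a camera adjusted p of 2.93e-18 (adjusted p = 0.0617 with an estimated correlation). Of 12 cell cycle inhibitor genes, 8 rose and 4 did not pass, with the same counts adjusted over the list alone. Cell cycle inhibitor genes had a median of 0.39 (0.43 in batch 1 and 0.29 in batch 2) at a camera adjusted p of 2.71e-05 (adjusted p = 0.00544 with an estimated correlation). Among these was the cyclin-dependent kinase inhibitor gene Cdkn2c (4.11 ± 0.296 to 8.22 ± 0.311 CPM, 0.996 in batch 1 and 1.09 in batch 2).

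Of 22 ribosome biogenesis genes, 18 fell and 4 did not pass, with the same counts adjusted over the list alone. A median of -0.33 (-0.31 in batch 1 and -0.29 in batch 2) went with a camera adjusted p of 1e-10 (adjusted p = 0.000653 with an estimated correlation). Of 14 LIN28 and oncofetal genes, 8 fell and 6 did not pass, and 1 rose and 9 fell adjusted over the list alone. Their median was -0.37 (-0.41 in batch 1 and -0.28 in batch 2), with a camera adjusted p of 9.34e-08 (adjusted p = 0.0676 with an estimated correlation). Besides Lin28a, Sall4 (35.0 ± 6.96 to 12.7 ± 1.104 CPM, -1.52 in batch 1 and -1.32 in batch 2) fell. Of 15 early contractile isoform genes, 9 fell and 6 did not pass, and 1 rose and 10 fell adjusted over the list alone. Early contractile isoform genes had a median of -0.36 (-0.38 in batch 1 and -0.28 in batch 2) at a camera adjusted p of 2.26e-05 (adjusted p = 0.0366 with an estimated correlation). The skeletal muscle actin gene Acta1 (716 ± 103 to 358 ± 21.6 CPM, -1.12 in batch 1 and -0.78 in batch 2) fell. Of 23 glycolysis genes, 2 rose, 13 fell and 8 did not pass, and 3 rose and 16 fell adjusted over the list alone. A median of -0.35 (-0.36 in batch 1 and -0.30 in batch 2) went with a camera adjusted p of 2.18e-07 (adjusted p = 0.251 with an estimated correlation). Of 29 fatty acid oxidation genes, 11 rose, 1 fell and 17 did not pass, and 15 rose and 1 fell adjusted over the list alone. Their median was 0.25 (0.37 in batch 1 and 0.092 in batch 2), with a camera adjusted p of 2.26e-05 (adjusted p = 0.219 with an estimated correlation).

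Of the 38 lists tested, 23 passed with camera, 14 upward and 9 downward, and 5 of these also with an estimated correlation. Mitochondrially encoded genes (median 0.32, 0.44 in batch 1 and -0.12 in batch 2, camera adjusted p = 0.0261, adjusted p = 0.5 with an estimated correlation) and macrophage genes (median 0.81, 1.68 in batch 1 and 0.50 in batch 2, camera adjusted p = 0.0187, adjusted p = 0.519 with an estimated correlation) passed upward. The macrophage median was 0.73 with members at 0 counts set to their bound. Without E10.5 replicate 1, the median was 0.17 (camera adjusted p = 0.0665) for mitochondrially encoded genes. Without E10.5 replicate 3 and without replicate 4, the macrophage median was 0.45 and 0.75 (camera adjusted p = 0.0943 and 0.0751). Without E9.5 replicate 1, the median was 2.70 for macrophage genes. Without E9.5 replicate 2, the median was 0.23 (camera adjusted p = 0.12) for mitochondrially encoded genes and 0.40 (camera adjusted p = 0.131) for macrophage genes. Without E9.5 replicate 3, the median was 0.33 (camera adjusted p = 0.111) for mitochondrially encoded genes and 0.51 (camera adjusted p = 0.107) for macrophage genes.

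Of the mevalonate pathway enzymes reported, 1 of 8 fell, with the same count adjusted over the list alone. This was Mvd (42.3 ± 0.437 to 30.9 ± 2.51 CPM, log2 fold change -0.45 ± 0.0934, adjusted p = 0.00179, -0.53 in batch 1 and -0.36 in batch 2). The log2 fold changes of the other 7, which did not pass, ran from -0.28 ± 0.118 for Fdps to 0.14 ± 0.0853 for Hmgcs1, with edgeR adjusted p from 0.112 to 0.958. The list had a median of -0.050 (-0.027 in batch 1 and -0.071 in batch 2) and a camera adjusted p of 0.334 (adjusted p = 0.654 with an estimated correlation). This median ran from -0.088 (with the replicate number as a block, adjusted p = 0.206) to -0.018 (with library totals only, adjusted p = 0.384) over the alternatives and did not pass in any. The Hmgcs1 and Idi1 calls were gained within batch 1, as rises (0.20 and 0.23, adjusted p = 0.0116 and 0.017). The Mvd call was lost within batch 2 (1 library at E9.5). The Fdps call was gained without E10.5 replicate 4 (-0.36, adjusted p = 0.0478), with the batch as a term (-0.33, adjusted p = 0.00805) and within batch 1 (adjusted p = 0.00215), and with replicates 1 to 3 only. Over all genes, 3446 of the 18885 genes tested passed (edgeR adjusted p under 0.05), 2007 higher and 1439 lower, and 825 of them changed at least 2-fold. Within batch 1 and batch 2 (1 library at E9.5), 6456 and 1232 genes passed, and without E9.5 replicate 3 the count was 2260.

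Between E10.5 (n = 4) and E12.5 (n = 4), 12 of 13 fibroblast genes and 7 of 12 coronary endothelial genes rose, while 14 of 14 LIN28 and oncofetal genes, 21 of 22 ribosome biogenesis genes and 24 of 32 DNA replication genes fell, and these lists passed with camera at either correlation. Fbln5, which organises elastic fibres, rose from 2.38 ± 1.12 to 102 ± 10.3 CPM (log2 fold change 5.44 ± 0.308, edgeR adjusted p = 5.69e-09, with 6.14 in batch 1 and 4.96 in batch 2), and Eln, which encodes elastin itself, from 22.9 ± 8.02 to 571 ± 40.7 CPM (log2 fold change 4.64 ± 0.288, edgeR adjusted p = 1.28e-08, with 5.25 in batch 1 and 4.24 in batch 2). Mgp, an inhibitor of calcification, rose from 1.14 ± 0.548 to 30.6 ± 4.72 CPM (log2 fold change 4.76 ± 0.219, edgeR adjusted p = 8.69e-11, with 5.18 in batch 1 and 4.36 in batch 2). Trim71, a regulator of early embryonic cells that is repressed by let-7, fell from 27.2 ± 1.33 to 4.30 ± 1.03 CPM (log2 fold change -2.66 ± 0.203, edgeR adjusted p = 2.58e-08, with -2.56 in batch 1 and -2.71 in batch 2).

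Of 13 fibroblast genes, 12 rose and 1 did not pass, with the same counts adjusted over the list alone. Fibroblast genes had a median of 1.67 (1.62 in batch 1 and 1.83 in batch 2) at a camera adjusted p of 1.2e-24 (adjusted p = 0.00041 with an estimated correlation). The collagen cross-linking enzyme gene Lox (4.05 ± 0.908 to 55.5 ± 1.86 CPM, 3.54 in batch 1 and 4.07 in batch 2) was among them. Of 39 extracellular matrix genes, 22 rose, 6 fell and 11 did not pass, and 22 rose and 7 fell adjusted over the list alone. A median of 0.71 (0.64 in batch 1 and 0.76 in batch 2) went with a camera adjusted p of 5.14e-15 (adjusted p = 0.0944 with an estimated correlation). Of 12 coronary endothelial genes, 7 rose, 1 fell and 4 did not pass, and 9 rose and 1 fell adjusted over the list alone. Their median was 1.71 (1.62 in batch 1 and 1.46 in batch 2), with a camera adjusted p of 1.51e-06 (adjusted p = 0.0264 with an estimated correlation). The peptide hormone gene Apln (0.927 ± 0.189 to 7.33 ± 0.750 CPM, 3.23 in batch 1 and 2.86 in batch 2) and the water channel gene Aqp1 (14.4 ± 0.662 to 60.5 ± 4.10 CPM, 2.18 in batch 1 and 2.04 in batch 2) rose. Of 4 adult globin genes, 4 rose, with the same counts adjusted over the list alone. Adult globin genes had a median of 3.64 (2.86 in batch 1 and 3.49 in batch 2) at a camera adjusted p of 0.000242 (adjusted p = 0.149 with an estimated correlation). Hbb-bt (39.9 ± 5.89 to 657 ± 233 CPM, 3.27 in batch 1 and 4.10 in batch 2) is an example, and reads of the near-identical adult globin genes may be shared between them. Of 29 fatty acid oxidation genes, 18 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone. A median of 0.34 (0.37 in batch 1 and 0.34 in batch 2) went with a camera adjusted p of 9.8e-06 (adjusted p = 0.175 with an estimated correlation). The share of globin counts was 1.19 ± 0.331% at E10.5 and 3.52 ± 1.47% at E12.5.

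Of 14 LIN28 and oncofetal genes, 14 fell, with the same counts adjusted over the list alone. Their median was -0.92 (-0.92 in batch 1 and -0.99 in batch 2), with a camera adjusted p of 5.09e-22 (adjusted p = 0.00245 with an estimated correlation). The chromatin factor gene Hmga2 (305 ± 15.4 to 118 ± 4.12 CPM, -1.34 in batch 1 and -1.38 in batch 2) fell. Of 22 ribosome biogenesis genes, 21 fell and 1 did not pass, with the same counts adjusted over the list alone. Ribosome biogenesis genes had a median of -0.59 (-0.52 in batch 1 and -0.59 in batch 2) at a camera adjusted p of 1.41e-16 (adjusted p = 6.47e-05 with an estimated correlation). The nucleolar protein gene Ncl (979.6 ± 50.5 to 576 ± 22.2 CPM, -0.69 in batch 1 and -0.79 in batch 2) is an example. Of 32 DNA replication genes, 24 fell and 8 did not pass, and 25 fell adjusted over the list alone. A median of -0.37 (-0.30 in batch 1 and -0.36 in batch 2) went with a camera adjusted p of 1.1e-10 (adjusted p = 0.0292 with an estimated correlation). The helicase subunit gene Mcm4 (162 ± 5.85 to 112 ± 7.29 CPM, -0.48 in batch 1 and -0.54 in batch 2) fell. Of 30 mitosis genes, 20 fell and 10 did not pass, and 21 fell adjusted over the list alone. Their median was -0.31 (-0.23 in batch 1 and -0.33 in batch 2), with a camera adjusted p of 1.51e-06 (adjusted p = 0.196 with an estimated correlation). Top2a (502 ± 33.8 to 339 ± 33.3 CPM, -0.51 in batch 1 and -0.53 in batch 2), which encodes a topoisomerase of dividing cells, was among them. Of 13 cholesterol branch genes, 11 fell and 2 did not pass, and 12 fell adjusted over the list alone. Cholesterol branch genes had a median of -0.35 (-0.31 in batch 1 and -0.49 in batch 2) at a camera adjusted p of 1.56e-05 (adjusted p = 0.117 with an estimated correlation). Cyp51 (98.2 ± 2.87 to 68.3 ± 2.54 CPM, -0.47 in batch 1 and -0.54 in batch 2) fell.

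With camera 20 of the 38 lists passed, 14 upward and 6 downward, and 5 of them with an estimated correlation. Cell cycle inhibitor genes (median 0.43, 0.33 in batch 1 and 0.41 in batch 2, camera adjusted p = 0.0122, adjusted p = 0.0874 with an estimated correlation) and core sarcomere genes (median 0.21, 0.26 in batch 1 and 0.21 in batch 2, camera adjusted p = 0.00919, adjusted p = 0.149 with an estimated correlation) passed upward. Endothelial genes (median 0.40, 0.42 in batch 1 and 0.36 in batch 2, camera adjusted p = 0.00185, adjusted p = 0.117 with an estimated correlation) and macrophage genes (median 1.26, 2.64 in batch 1 and 0.73 in batch 2, camera adjusted p = 0.000443, adjusted p = 0.45 with an estimated correlation) passed upward. Mural cell genes (median 0.32, 1.003 in batch 1 and 0.20 in batch 2, camera adjusted p = 0.00915, adjusted p = 0.175 with an estimated correlation) passed upward. Without E10.5 replicate 3, the median was 0.50 for mural cell genes. Without E10.5 replicate 4, the median was 1.97 for macrophage genes and 0.82 for mural cell genes.

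Among the mevalonate pathway enzymes reported, 6 of 8 fell, with the same count adjusted over the list alone. Acat2 (41.0 ± 2.65 to 30.8 ± 0.813 CPM, log2 fold change -0.41 ± 0.0756, adjusted p = 0.000242, -0.38 in batch 1 and -0.45 in batch 2), Hmgcs1 (214 ± 8.53 to 156 ± 2.82 CPM, log2 fold change -0.46 ± 0.0790, adjusted p = 0.000141, -0.42 in batch 1 and -0.47 in batch 2), Mvk (27.4 ± 1.92 to 22.4 ± 1.78 CPM, log2 fold change -0.29 ± 0.103, adjusted p = 0.0325, -0.24 in batch 1 and -0.27 in batch 2), Mvd (30.9 ± 2.51 to 23.3 ± 1.63 CPM, log2 fold change -0.40 ± 0.0875, adjusted p = 0.00119, -0.25 in batch 1 and -0.51 in batch 2), Idi1 (41.5 ± 2.92 to 26.7 ± 1.60 CPM, log2 fold change -0.64 ± 0.0815, adjusted p = 5.08e-06, -0.61 in batch 1 and -0.59 in batch 2) and Fdps (49.7 ± 7.05 to 37.8 ± 4.18 CPM, log2 fold change -0.40 ± 0.110, adjusted p = 0.00751, -0.37 in batch 1 and -0.50 in batch 2) fell (edgeR). Pmvk (0.17 ± 0.106, adjusted p = 0.217, 0.12 in batch 1 and 0.079 in batch 2) and Ggps1 (-0.043 ± 0.0829, adjusted p = 0.716, -0.047 in batch 1 and 0.020 in batch 2) did not pass (log2 fold changes). The list median was -0.40 (-0.37 in batch 1 and -0.47 in batch 2), with a camera adjusted p of 0.00152 (adjusted p = 0.215 with an estimated correlation). The Mvk call was lost without E10.5 replicate 1 (-0.25, adjusted p = 0.101), without E10.5 replicate 3 (-0.28, adjusted p = 0.0617), without E12.5 replicate 1 (-0.24, adjusted p = 0.104), without E12.5 replicate 2 (-0.28, adjusted p = 0.0705), within batch 2 (adjusted p = 0.146) and within batch 1 (1 library at E12.5, adjusted p = 0.103), and with libraries thinned to the smallest. The Pmvk call was gained with replicates 1 to 3 only. The Fdps call was lost with replicates 1 to 3 only. In all, 7181 of the 18885 genes tested passed (edgeR adjusted p under 0.05), 3772 higher and 3409 lower, and 1638 of them changed at least 2-fold. Within batch 1 (1 library at E12.5) and batch 2, 5936 and 5563 genes passed.

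Between E12.5 (n = 4) and E14.5 (n = 3), 13 of 29 fatty acid oxidation genes and 8 of 12 coronary endothelial genes rose, while 9 of 10 primitive erythroid genes, 11 of 14 LIN28 and oncofetal genes and 10 of 13 cholesterol branch genes fell, and these lists passed with camera at either correlation. Ermap, a red cell membrane protein gene, fell from 93.7 ± 36.5 to 4.18 ± 1.61 CPM (log2 fold change -4.47 ± 0.342, edgeR adjusted p = 9.35e-07, with -4.69 in batch 2), and the blood group gene Kel from 95.2 ± 40.2 to 4.88 ± 2.61 CPM (log2 fold change -4.27 ± 0.423, edgeR adjusted p = 1.3e-05, with -4.49 in batch 2). Fabp4, which binds fatty acids in capillary endothelium, rose from 6.87 ± 2.69 to 76.4 ± 10.6 CPM (log2 fold change 3.48 ± 0.499, edgeR adjusted p = 0.000354, with 3.24 in batch 2). Myom2, a gene of the sarcomere M-band, rose from 4.89 ± 0.710 to 34.6 ± 5.42 CPM (log2 fold change 2.82 ± 0.205, edgeR adjusted p = 2.61e-07, with 2.84 in batch 2), and Ckm, a muscle creatine kinase gene, from 47.7 ± 10.7 to 360.4 ± 128 CPM (log2 fold change 2.92 ± 0.406, edgeR adjusted p = 0.000262, with 2.80 in batch 2).

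Of 10 primitive erythroid genes, 9 fell and 1 did not pass, and 10 fell adjusted over the list alone. A median of -3.84 (-4.06 in batch 2) went with a camera adjusted p of 3.37e-20 (adjusted p = 0.0209 with an estimated correlation). Slc4a1 (652 ± 231 to 58.1 ± 16.3 CPM, -3.68 in batch 2), the anion exchanger of red cells, fell too. Of 8 megakaryocyte genes, 7 fell and 1 did not pass, and 8 fell adjusted over the list alone. Their median was -1.56 (-1.77 in batch 2), with a camera adjusted p of 1.99e-08 (adjusted p = 0.0615 with an estimated correlation). An example is the platelet integrin gene Itga2b (50.4 ± 15.4 to 14.7 ± 4.12 CPM, -1.93 in batch 2). The share of globin counts was 3.52 ± 1.47% at E12.5 and 1.04 ± 0.554% at E14.5. Of 14 LIN28 and oncofetal genes, 11 fell and 3 did not pass, and 13 fell adjusted over the list alone. LIN28 and oncofetal genes had a median of -0.78 (-0.76 in batch 2) at a camera adjusted p of 1.26e-23 (adjusted p = 0.00301 with an estimated correlation). Hmga2 (118 ± 4.12 to 39.6 ± 5.83 CPM, -1.57 in batch 2) fell. Of 22 ribosome biogenesis genes, 13 fell and 9 did not pass, and 15 fell adjusted over the list alone. A median of -0.31 (-0.29 in batch 2) went with a camera adjusted p of 7.14e-08 (adjusted p = 0.00301 with an estimated correlation). Of 32 DNA replication genes, 13 fell and 19 did not pass, and 18 fell adjusted over the list alone. Their median was -0.23 (-0.21 in batch 2), with a camera adjusted p of 1.09e-08 (adjusted p = 0.0475 with an estimated correlation). Mcm4 (112 ± 7.29 to 84.1 ± 4.12 CPM, -0.39 in batch 2) fell. Of 10 endocardial and valve genes, 8 fell and 2 did not pass, and 1 rose and 8 fell adjusted over the list alone. Endocardial and valve genes had a median of -0.49 (-0.45 in batch 2) at a camera adjusted p of 1.18e-06 (adjusted p = 0.00334 with an estimated correlation). The hyaluronan-linking protein gene Hapln1 (156 ± 9.01 to 40.7 ± 12.1 CPM, -1.90 in batch 2) fell. Of 13 cholesterol branch genes, 10 fell and 3 did not pass, and 12 fell adjusted over the list alone. A median of -0.37 (-0.30 in batch 2) went with a camera adjusted p of 1.67e-10 (adjusted p = 0.0209 with an estimated correlation). Fdft1 (51.5 ± 2.75 to 33.8 ± 1.06 CPM, -0.60 in batch 2) fell.

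Of 29 fatty acid oxidation genes, 13 rose and 16 did not pass, and 19 rose adjusted over the list alone. Their median was 0.30 (0.33 in batch 2), with a camera adjusted p of 3.83e-12 (adjusted p = 0.0365 with an estimated correlation). The coactivator gene Ppargc1a (67.1 ± 2.10 to 99.7 ± 5.47 CPM, 0.59 in batch 2) rose. Of 12 coronary endothelial genes, 8 rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone. Coronary endothelial genes had a median of 1.34 (1.27 in batch 2) at a camera adjusted p of 9.16e-09 (adjusted p = 0.0101 with an estimated correlation).

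With camera 24 of the 38 lists passed, 11 upward and 13 downward, and 8 of them with an estimated correlation. Mitosis genes (median -0.15, -0.10 in batch 2, camera adjusted p = 0.00164, adjusted p = 0.415 with an estimated correlation) passed downward. Core sarcomere genes (median 0.15, 0.12 in batch 2, camera adjusted p = 0.00796, adjusted p = 0.11 with an estimated correlation) and endothelial genes (median 0.13, 0.12 in batch 2, camera adjusted p = 0.0215, adjusted p = 0.217 with an estimated correlation) passed upward. Adult globin genes (median -0.081, -0.31 in batch 2, camera adjusted p = 0.915, with a mean of 0.34 and a test that pointed upward) did not pass. Without E12.5 replicate 2, the median was 0.10 (camera adjusted p = 0.0792) for endothelial genes. Without E14.5 replicate 3, the median was -0.10 for mitosis genes and 0.10 for core sarcomere genes.

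Of the mevalonate pathway enzymes reported, 6 of 8 fell, with the same count adjusted over the list alone. Acat2 (30.8 ± 0.813 to 20.1 ± 1.76 CPM, log2 fold change -0.61 ± 0.0835, adjusted p = 4.99e-05, -0.61 in batch 2), Hmgcs1 (156 ± 2.82 to 121 ± 14.1 CPM, log2 fold change -0.36 ± 0.0859, adjusted p = 0.00652, -0.35 in batch 2), Mvk (22.4 ± 1.78 to 16.4 ± 1.57 CPM, log2 fold change -0.46 ± 0.113, adjusted p = 0.00889, -0.42 in batch 2), Mvd (23.3 ± 1.63 to 17.6 ± 1.75 CPM, log2 fold change -0.41 ± 0.0961, adjusted p = 0.0063, -0.39 in batch 2), Idi1 (26.7 ± 1.60 to 18.8 ± 2.04 CPM, log2 fold change -0.50 ± 0.0897, adjusted p = 0.0007, -0.46 in batch 2) and Fdps (37.8 ± 4.18 to 27.9 ± 2.32 CPM, log2 fold change -0.44 ± 0.120, adjusted p = 0.0175, -0.48 in batch 2) fell (edgeR). Pmvk (-0.12 ± 0.115, adjusted p = 0.568, -0.19 in batch 2) and Ggps1 (0.059 ± 0.0895, adjusted p = 0.736, 0.087 in batch 2) did not pass (log2 fold changes). The list median was -0.44 (-0.42 in batch 2), with a camera adjusted p of 1.4e-06 (adjusted p = 0.0615 with an estimated correlation). The Hmgcs1 call was lost without E14.5 replicate 3 (-0.28, adjusted p = 0.0566). The Mvk call was lost without E14.5 replicate 1 (-0.38, adjusted p = 0.0523). The Fdps call was lost without E12.5 replicate 3 (-0.37, adjusted p = 0.0561) and without E14.5 replicate 3 (-0.37, adjusted p = 0.0969). Over all genes, 2803 of the 18885 genes tested passed (edgeR adjusted p under 0.05), 1187 higher and 1616 lower, and 633 of them changed at least 2-fold. Of those that passed, 42.3% were higher, against 62.5% with library totals only, and the count was 1771 without E14.5 replicate 3. Within batch 2, 3041 genes passed.

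Between E14.5 (n = 3) and E16.5 (n = 4), 29 of 32 nuclear respiratory chain genes, 20 of 20 citric acid cycle genes, 21 of 29 fatty acid oxidation genes and 19 of 26 core sarcomere genes rose, while 10 of 14 LIN28 and oncofetal genes and 5 of 10 endocardial and valve genes fell, and these lists passed with camera at either correlation. All libraries of both stages belong to batch 2, but differ in Gh (below). Plin4, a lipid droplet protein gene, rose from 0.839 ± 0.115 to 11.1 ± 4.40 CPM (log2 fold change 3.73 ± 0.344, edgeR adjusted p = 6.49e-07). Kcnip2, a subunit of the transient outward potassium channel, rose from 3.94 ± 2.15 to 40.7 ± 9.78 CPM (log2 fold change 3.39 ± 0.382, edgeR adjusted p = 2.25e-05), and Ckmt2, a mitochondrial creatine kinase gene of muscle, from 7.70 ± 0.587 to 46.03 ± 3.57 CPM (log2 fold change 2.58 ± 0.114, edgeR adjusted p = 5.92e-11). Col2a1, a fibrillar collagen gene of cartilage and valve cushions, fell from 33.1 ± 7.71 to 5.48 ± 0.839 CPM (log2 fold change -2.59 ± 0.172, edgeR adjusted p = 8.05e-08), and Hmga2 from 39.6 ± 5.83 to 13.1 ± 1.66 CPM (log2 fold change -1.60 ± 0.0956, edgeR adjusted p = 4.77e-09).

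Of 32 nuclear respiratory chain genes, 29 rose and 3 did not pass, and 32 rose adjusted over the list alone. A median of 0.61 went with a camera adjusted p of 3.35e-30 (adjusted p = 0.0383 with an estimated correlation). Uqcrc1 (378 ± 39.9 to 626 ± 53.9 CPM), of complex III, rose. Of 20 citric acid cycle genes, 20 rose, with the same counts adjusted over the list alone. Their median was 0.53, with a camera adjusted p of 6.11e-25 (adjusted p = 0.014 with an estimated correlation). Of 29 fatty acid oxidation genes, 21 rose, 1 fell and 7 did not pass, and 24 rose and 2 fell adjusted over the list alone. Fatty acid oxidation genes had a median of 0.53 at a camera adjusted p of 7.06e-21 (adjusted p = 0.0125 with an estimated correlation). Acadm (235 ± 9.71 to 405 ± 15.3 CPM) rose. Of 26 core sarcomere genes, 19 rose and 7 did not pass, and 23 rose adjusted over the list alone. A median of 0.49 went with a camera adjusted p of 2.28e-15 (adjusted p = 0.00101 with an estimated correlation). The cardiac troponin gene Tnni3 (548 ± 62.7 to 1027 ± 100.05 CPM) rose. Of 28 calcium handling genes, 6 rose, 1 fell and 21 did not pass, and 10 rose and 2 fell adjusted over the list alone. Their median was 0.22, with a camera adjusted p of 0.00132 (adjusted p = 0.0604 with an estimated correlation). The calcium pump gene Atp2a2 (1831 ± 88.7 to 2596 ± 29.9 CPM) is an example. Of 13 mitochondrially encoded genes, 5 rose and 8 did not pass, and 6 rose adjusted over the list alone. Mitochondrially encoded genes had a median of 0.41 at a camera adjusted p of 0.00765 (adjusted p = 0.555 with an estimated correlation). The share of counts from mitochondrial genes was 4.34 ± 0.536% at E14.5 and 5.56 ± 0.740% at E16.5.

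Of 10 mural cell genes, 6 rose and 4 did not pass, and 10 rose adjusted over the list alone. A median of 1.16 went with a camera adjusted p of 3.43e-10 (adjusted p = 0.00991 with an estimated correlation). The potassium channel gene Kcnj8 (12.9 ± 2.30 to 27.9 ± 3.16 CPM) rose. Of 12 coronary endothelial genes, 5 rose and 7 did not pass, and 6 rose adjusted over the list alone. Their median was 0.74, with a camera adjusted p of 8.46e-07 (adjusted p = 0.017 with an estimated correlation). Gpihbp1 (6.62 ± 1.84 to 26.9 ± 3.68 CPM), which holds lipoprotein lipase in capillaries, rose. Of 14 LIN28 and oncofetal genes, 10 fell and 4 did not pass, with the same counts adjusted over the list alone. LIN28 and oncofetal genes had a median of -0.58 at a camera adjusted p of 7.31e-14 (adjusted p = 0.014 with an estimated correlation). Mycn (52.1 ± 2.39 to 32.8 ± 1.25 CPM) was among them. Of 32 DNA replication genes, 14 fell and 18 did not pass, and 16 fell adjusted over the list alone. A median of -0.20 went with a camera adjusted p of 0.000181 (adjusted p = 0.176 with an estimated correlation). Of 30 mitosis genes, 9 fell and 21 did not pass, and 10 fell adjusted over the list alone. Their median was -0.18, with a camera adjusted p of 0.000383 (adjusted p = 0.406 with an estimated correlation). Ccnb1 (139 ± 6.56 to 108 ± 8.68 CPM) fell. Of 10 endocardial and valve genes, 1 rose, 5 fell and 4 did not pass, and 1 rose and 6 fell adjusted over the list alone. Endocardial and valve genes had a median of -0.30 at a camera adjusted p of 0.000714 (adjusted p = 0.0233 with an estimated correlation). Hapln1 (40.7 ± 12.1 to 10.8 ± 2.94 CPM) fell.

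With camera 19 of the 38 lists passed, 12 upward and 7 downward, and 8 of them with an estimated correlation. Second heart field genes (median -0.37, camera adjusted p = 0.0023, adjusted p = 0.133 with an estimated correlation) and insulin-like growth and imprinted genes (median -0.28, camera adjusted p = 0.00765, adjusted p = 0.0604 with an estimated correlation) passed downward. Primitive erythroid genes (median -1.27, camera adjusted p = 0.00124, adjusted p = 0.464 with an estimated correlation) passed downward. Adult globin genes (median 1.25, camera adjusted p = 0.0451, adjusted p = 0.473 with an estimated correlation) and glycolysis genes (median 0.089, camera adjusted p = 0.0303, adjusted p = 0.644 with an estimated correlation) passed upward. Wnt5a (65.6 ± 1.81 to 32.0 ± 2.87 CPM), Igf1 (89.3 ± 11.1 to 56.1 ± 7.58 CPM) and the embryonic globin gene Hba-x (517 ± 328 to 32.1 ± 17.8 CPM) fell. The share of globin counts was 1.04 ± 0.554% at E14.5 and 1.503 ± 0.519% at E16.5. For primitive erythroid genes, without mitochondrial and globin genes the median was -0.72 (camera adjusted p = 0.167). For adult globin genes, with RLE size factors the median was 1.27 (camera adjusted p = 0.0534). For glycolysis genes, with library totals only the median was -0.038 (camera adjusted p = 0.157). Without E14.5 replicate 1, the median was 0.14 for glycolysis genes. Without E14.5 replicate 2, the median was 0.15 for glycolysis genes. Without E14.5 replicate 3, the median was 1.02 (camera adjusted p = 0.168) for adult globin genes and -0.0061 (camera adjusted p = 0.274) for glycolysis genes. Without E16.5 replicate 1, the median was -0.0090 (camera adjusted p = 0.156) for glycolysis genes. Without E16.5 replicate 3, the median was 0.997 (camera adjusted p = 0.101) for adult globin genes, and the median was 0.18 for glycolysis genes. Without E16.5 replicate 4, the median was 0.16 for glycolysis genes.

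Of the mevalonate pathway enzymes reported, 1 of 8 fell, Acat2 (20.1 ± 1.76 to 16.9 ± 1.78 CPM, log2 fold change -0.25 ± 0.0835, adjusted p = 0.0401), and 0 of 8 passed adjusted over the list alone (edgeR). Over all genes Acat2 passed by limma-voom and DESeq2 as well. The log2 fold changes of the other 7, which did not pass, ran from -0.088 ± 0.0898 for Idi1 to 0.24 ± 0.113 for Mvk, with edgeR adjusted p from 0.146 to 0.799. The list median was -0.065, with a camera adjusted p of 0.733 (adjusted p = 0.851 with an estimated correlation). Over the alternatives the median ran from -0.19 (with library totals only, adjusted p = 0.464) to -0.0093 (without E16.5 replicate 3, adjusted p = 0.878) and did not pass in any. The Acat2 call was lost without E14.5 replicate 1 (-0.20, adjusted p = 0.191), without E14.5 replicate 2 (-0.24, adjusted p = 0.128), without E16.5 replicate 1 (-0.23, adjusted p = 0.0865), without E16.5 replicate 2 (-0.23, adjusted p = 0.0864), without E16.5 replicate 3 (-0.22, adjusted p = 0.0875) and within batch 2 (adjusted p = 0.0509), and with RLE size factors, no filter on low counts and only these 2 stages in the fit. In all, 3562 of the 18885 genes tested passed (edgeR adjusted p under 0.05), 1911 higher and 1651 lower, and 645 of them changed at least 2-fold. Of these, 53.6% were higher, against 24.4% with library totals only, where the median over all genes was -0.15 in place of -0.024. Without E14.5 replicate 1 and without replicate 2 the counts were 2058 and 2225.

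From E9.5 (n = 3) to E16.5 (n = 4), 27 of 29 fatty acid oxidation genes, 18 of 26 core sarcomere genes, 11 of 13 fibroblast genes and 10 of 12 coronary endothelial genes rose, while 14 of 14 LIN28 and oncofetal genes, 22 of 22 ribosome biogenesis genes and 31 of 32 DNA replication genes fell, and these lists passed with camera at either correlation. Myom2 rose from 0.549 ± 0.128 to 188 ± 28.5 CPM (log2 fold change 8.41 ± 0.311, edgeR adjusted p = 6.99e-13, with 8.09 in batch 2). Lin28a fell from 140.1 ± 44.1 to 0.456 ± 0.321 CPM (log2 fold change -8.26 ± 0.366, edgeR adjusted p = 1.84e-11, with -7.90 in batch 2), and Col2a1 from 769 ± 175 to 5.48 ± 0.839 CPM (log2 fold change -7.13 ± 0.196, edgeR adjusted p = 4.17e-15, with -6.80 in batch 2).

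Of 29 fatty acid oxidation genes, 27 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. A median of 1.26 (1.31 in batch 2) went with a camera adjusted p of 2.78e-19 (adjusted p = 0.0121 with an estimated correlation). Citric acid cycle genes (median 0.98, 0.90 in batch 2, camera adjusted p = 2.5e-10, adjusted p = 0.0872 with an estimated correlation) and nuclear respiratory chain genes (median 1.13, 1.02 in batch 2, camera adjusted p = 3.05e-12, adjusted p = 0.154 with an estimated correlation) passed upward. Mitochondrially encoded genes (median 1.31, 0.99 in batch 2, camera adjusted p = 0.00125, adjusted p = 0.302 with an estimated correlation) passed upward. Of 26 core sarcomere genes, 18 rose, 4 fell and 4 did not pass, with the same counts adjusted over the list alone. Their median was 0.75 (0.82 in batch 2), with a camera adjusted p of 7.44e-05 (adjusted p = 0.0375 with an estimated correlation). Of 28 calcium handling genes, 16 rose, 8 fell and 4 did not pass, and 16 rose and 9 fell adjusted over the list alone. Calcium handling genes had a median of 0.39 (0.49 in batch 2) at a camera adjusted p of 0.00226 (adjusted p = 0.078 with an estimated correlation). The calcium store protein gene Casq2 (6.88 ± 3.34 to 905 ± 46.2 CPM, 6.45 in batch 2) rose. Of 15 early contractile isoform genes, 4 rose, 9 fell and 2 did not pass, with the same counts adjusted over the list alone. A median of -0.67 (-0.28 in batch 2) went with a camera adjusted p of 0.00393 (adjusted p = 0.111 with an estimated correlation). Acta1 (716 ± 103 to 80.5 ± 7.26 CPM, -2.97 in batch 2) fell. The share of counts from mitochondrial genes was 2.20 ± 0.168% at E9.5 and 5.56 ± 0.740% at E16.5.

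Of 14 LIN28 and oncofetal genes, 14 fell, with the same counts adjusted over the list alone. Their median was -3.03 (-2.93 in batch 2), with a camera adjusted p of 3.07e-30 (adjusted p = 0.00155 with an estimated correlation). Hmga2 (396 ± 17.0 to 13.1 ± 1.66 CPM, -4.87 in batch 2) is an example. Of 22 ribosome biogenesis genes, 22 fell, with the same counts adjusted over the list alone. Ribosome biogenesis genes had a median of -1.24 (-1.16 in batch 2) at a camera adjusted p of 1.65e-18 (adjusted p = 4.18e-05 with an estimated correlation). Of 32 DNA replication genes, 1 rose and 31 fell, with the same counts adjusted over the list alone. A median of -0.79 (-0.77 in batch 2) went with a camera adjusted p of 2.92e-13 (adjusted p = 0.0142 with an estimated correlation). Mcm4 (165 ± 1.28 to 66.1 ± 0.570 CPM, -1.29 in batch 2) fell. Of 30 mitosis genes, 28 fell and 2 did not pass, with the same counts adjusted over the list alone. Their median was -0.79 (-0.72 in batch 2), with a camera adjusted p of 7.75e-10 (adjusted p = 0.0872 with an estimated correlation). Ccnb1 (249.8 ± 13.4 to 108 ± 8.68 CPM, -1.100 in batch 2) fell. Of 12 cell cycle inhibitor genes, 9 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone. Cell cycle inhibitor genes had a median of 0.97 (0.89 in batch 2) at a camera adjusted p of 0.00227 (adjusted p = 0.0309 with an estimated correlation). Cdkn1a (18.6 ± 3.42 to 59.1 ± 6.38 CPM, 1.41 in batch 2) rose. Of 19 second heart field genes, 3 rose, 14 fell and 2 did not pass, with the same counts adjusted over the list alone. A median of -1.24 (-0.79 in batch 2) went with a camera adjusted p of 0.00226 (adjusted p = 0.114 with an estimated correlation). Fgf10 (10.9 ± 3.14 to 0.615 ± 0.213 CPM, -3.77 in batch 2) fell.

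Of 13 fibroblast genes, 11 rose and 2 did not pass, with the same counts adjusted over the list alone. Their median was 4.25 (4.66 in batch 2), with a camera adjusted p of 1.11e-18 (adjusted p = 0.00155 with an estimated correlation). Of 12 coronary endothelial genes, 10 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. Coronary endothelial genes had a median of 3.56 (3.03 in batch 2) at a camera adjusted p of 1.83e-06 (adjusted p = 0.0197 with an estimated correlation). Extracellular matrix genes (median 1.72, 1.69 in batch 2, camera adjusted p = 3.67e-12, adjusted p = 0.0876 with an estimated correlation) and endothelial genes (median 0.53, 0.45 in batch 2, camera adjusted p = 0.0175, adjusted p = 0.168 with an estimated correlation) passed upward. Epicardial genes (median 2.17, 1.69 in batch 2, camera adjusted p = 0.00178, adjusted p = 0.185 with an estimated correlation) and mural cell genes (median 1.46, 2.69 in batch 2, camera adjusted p = 1.32e-05, adjusted p = 0.0197 with an estimated correlation) passed upward. Adult globin genes (median 6.18, 5.67 in batch 2, camera adjusted p = 0.00987, adjusted p = 0.246 with an estimated correlation) passed upward. Of 10 endocardial and valve genes, 2 rose, 6 fell and 2 did not pass, with the same counts adjusted over the list alone. A median of -0.74 (-0.78 in batch 2) went with a camera adjusted p of 0.00567 (adjusted p = 0.0482 with an estimated correlation). Hapln1 (456 ± 36.0 to 10.8 ± 2.94 CPM, -5.50 in batch 2) fell. Of 15 macrophage genes, 9 rose and 6 did not pass, and 10 rose adjusted over the list alone. Their median was 2.90 (1.75 in batch 2), with a camera adjusted p of 0.00383 (adjusted p = 0.45 with an estimated correlation). The macrophage median was 2.73 with members at 0 counts set to their bound. Of 10 primitive erythroid genes, 1 rose, 8 fell and 1 did not pass, with the same counts adjusted over the list alone. Primitive erythroid genes had a median of -4.26 (-4.22 in batch 2) at a camera adjusted p of 0.00383 (adjusted p = 0.383 with an estimated correlation). The share of globin counts was 0.647 ± 0.147% at E9.5 and 1.503 ± 0.519% at E16.5. Without E9.5 replicate 1, the median was 4.56 for macrophage genes. Without E9.5 replicate 2, the median was 2.47 for mural cell genes.

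With camera 25 of the 38 lists passed, 15 upward and 10 downward, and 10 of them with an estimated correlation. Protein prenylation genes (median -0.31, -0.15 in batch 2, camera adjusted p = 0.185) and SREBP and sterol uptake genes (median -0.00070, 0.27 in batch 2, camera adjusted p = 0.958, with a mean of -0.0079 and a test that pointed upward) did not pass. Glycolysis genes (median -0.22, -0.15 in batch 2, camera adjusted p = 0.362) and cardiac transcription factor genes (median -0.30, -0.12 in batch 2, camera adjusted p = 0.138) did not pass. Trabecular and secreted factor genes (median 0.57, 0.41 in batch 2, camera adjusted p = 0.95) and cytosolic ribosome genes (median -0.24, -0.30 in batch 2, camera adjusted p = 0.0841) did not pass. Insulin-like growth and imprinted genes (median -0.27, 0.013 in batch 2, camera adjusted p = 0.95, with a mean of 0.12 and a test that pointed upward) and megakaryocyte genes (median 0.72, 0.18 in batch 2, camera adjusted p = 0.869) did not pass. Neural crest and Schwann cell genes (median 1.73, 1.61 in batch 2, camera adjusted p = 0.0891) and neuronal genes (median 1.75, 0.78 in batch 2, camera adjusted p = 0.312) did not pass. Endoderm and liver genes (median -1.098, -0.55 in batch 2, camera adjusted p = 0.839) and lung epithelium genes (median -2.01, 0.57 in batch 2, camera adjusted p = 0.199) did not pass. Pharyngeal arch genes (median 2.27, 1.28 in batch 2, camera adjusted p = 0.221) did not pass. With members at 0 counts set to their bound, medians were 1.73 (neural crest and Schwann cell), 1.66 (neuronal) and 2.03 (pharyngeal arch). Without E16.5 replicate 4, the median was -0.28 (camera adjusted p = 0.0467) for cytosolic ribosome genes. Without E9.5 replicate 1, the median was -0.38 (camera adjusted p = 0.0262) for cardiac transcription factor genes and 1.80 (camera adjusted p = 0.0443) for neural crest and Schwann cell genes. With the batch as a term, cytosolic ribosome genes passed downward (median -0.32, camera adjusted p = 0.0133). The list of thymus and lymphoid genes had too few measured members to test.

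Of the mevalonate pathway enzymes reported, 6 of 8 fell, with the same count adjusted over the list alone. Acat2 (42.5 ± 1.74 to 16.9 ± 1.78 CPM, log2 fold change -1.33 ± 0.0825, adjusted p = 3.86e-11, -1.33 in batch 2), Hmgcs1 (195 ± 12.496 to 135 ± 14.2 CPM, log2 fold change -0.53 ± 0.0848, adjusted p = 1.86e-05, -0.61 in batch 2), Mvk (28.7 ± 1.58 to 19.4 ± 3.53 CPM, log2 fold change -0.57 ± 0.111, adjusted p = 0.000161, -0.51 in batch 2), Mvd (42.3 ± 0.437 to 18.2 ± 2.19 CPM, log2 fold change -1.21 ± 0.0945, adjusted p = 1.02e-09, -1.19 in batch 2), Idi1 (39.3 ± 2.31 to 17.7 ± 1.60 CPM, log2 fold change -1.15 ± 0.0885, adjusted p = 8.94e-10, -1.22 in batch 2) and Fdps (60.3 ± 7.83 to 26.8 ± 3.03 CPM, log2 fold change -1.17 ± 0.119, adjusted p = 4.57e-08, -1.34 in batch 2) fell (edgeR). Pmvk (-0.15 ± 0.115, adjusted p = 0.27, -0.26 in batch 2) and Ggps1 (-0.047 ± 0.0901, adjusted p = 0.662, -0.030 in batch 2) did not pass (log2 fold changes). The list median was -1.15 (-1.19 in batch 2), with a camera adjusted p of 0.000289 (adjusted p = 0.114 with an estimated correlation). The Pmvk call was gained with the batch as a term (-0.35, adjusted p = 0.00237). Of 13 cholesterol branch genes, 12 fell and 1 did not pass, with the same counts adjusted over the list alone. A median of -0.94 (-0.83 in batch 2) went with a camera adjusted p of 1.57e-06 (adjusted p = 0.0502 with an estimated correlation). In all, 12255 of the 18885 genes tested passed (edgeR adjusted p under 0.05), 6069 higher and 6186 lower, and 5454 of them changed at least 2-fold. Within batch 2 (1 library at E9.5), 10052 genes passed.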

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

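The criterion for a library apart was fixed in advance. In 13 of 165 groups of 4 libraries (stage totals, components, mevalonate enzymes and lists), 1 library lay apart from the other 3 by Dixon's criterion, where chance gives about 8.25. E12.5 replicate 3 had 45.6 M counts, against 36.4 to 37.8 M in the others of its stage, and E10.5 replicate 1 had 25280 genes detected, against 24706 to 24803. On the first component E16.5 replicate 2 lay at 66.6, against 70.6 to 70.8, and on the third E16.5 replicate 3 lay at -17.0, against -20.7 to -20.4. Acat2 stood at 44.96 CPM in E10.5 replicate 4, against 39.2 to 40.0 CPM, and at 19.6 CPM in E16.5 replicate 4, against 15.8 to 16.3 CPM. In that last library Mvk stood at 24.6 CPM, against 17.1 to 18.4 CPM. E12.5 replicate 3 had a mean log2 CPM of 6.13 over the cell cycle inhibitor genes, against 6.06 to 6.07, and of 7.97 over the nuclear respiratory chain genes, against 7.72 to 7.75. E12.5 replicate 1 had 6.30 over the trabecular and secreted factor genes, against 6.48 to 6.4999, and 5.84 over the endocardial and valve genes, against 5.73 to 5.74. E12.5 replicate 4, of batch 1, had 0.85 over the neural crest and Schwann cell genes, against 1.17 to 1.22, and E16.5 replicate 4 had 0.84 over the lung epithelium genes, against 0.076 to 0.17. Among the other named genes, 45 of 714 groups had 1 library apart, where chance gives about 35.7.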

How the results depend on the processing

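The tests with a batch term, within either batch and without batch genes were chosen after the results were seen. Of 9056 values of named genes under the alternatives, 8898 kept their call and direction, 148 were no longer past the threshold, 9 newly passed and 1 reversed, that of mt-Atp8 from E9.5 to E10.5 (-0.069 within batch 2, adjusted p = 0.944). With an adjusted p under 0.01 the genes that passed were 1924 for E10.5 with E9.5, 1501 for E14.5 with E12.5 and 1919 for E16.5 with E14.5. A fold of at least 2 left 825, 1638, 633, 645 and 5454 genes in the 5 comparisons, in the order of the report, by construction fewer. With an estimated correlation 5, 5, 8, 8 and 10 lists passed, and the mevalonate medians of -0.40, -0.44 and -1.15, the same values by construction, had adjusted p of 0.215, 0.0615 and 0.114. A filter of 10 CPM in 3 libraries, with fewer genes tested, left 15 lists for E10.5 with E9.5. With fits filtered anew, 1215 genes passed for that comparison within batch 2 (1 library at E9.5) and 6460 within batch 1, and the cause of the difference was not tested. Apart from leaving out libraries, the other alternatives for counts of genes stayed within 1.5 times the value reported.

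Values here follow the order of the report. Leaving out 1 library at a time gave 2260 to 3839, 6067 to 7191, 1771 to 2585, 2058 to 3849 and 11224 to 12634 genes. Lists that passed ranged over 20 to 23, 18 to 20, 21 to 25, 17 to 21 and 25 to 27. Mevalonate medians ranged from -0.08 to -0.02, -0.44 to -0.36, -0.48 to -0.38, -0.12 to -0.01 and -1.20 to -1.06. With the replicate number as a block, 3286, 7060, 2415, 3105 and 11927 genes and 23, 19, 25, 20 and 25 lists passed, with mevalonate medians of -0.09, -0.40, -0.42, -0.08 and -1.17. The numbers do not pair the libraries: of 16 same-numbered pairs over the 5 comparisons 4 had a correlation of deviations over 0.1 (range -0.78 to 0.66) and 2 matched best at their own number. Depth limits transcripts near the floor of 3 counts per library, and thinning to the smallest library kept every count of genes within 1.5 times.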

Other observations

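The tests of batch, macrophages, carried-over reads, red cells and heart muscle share were chosen after the results were seen, and those of GC content and length and of other splits before. Each library at E9.5 and E10.5 held both Xist, from the inactive X chromosome of female cells, at 128 to 466.2 CPM, and transcripts of 4 Y-linked genes, at 74.7 to 153 CPM. At E12.5 and later, 5 libraries (E12.5 replicates 1 and 4, E14.5 replicates 1 and 3, E16.5 replicate 2) had Xist at 473 to 770.3 CPM and the Y-linked genes at 0.212 to 4.61 CPM, and the other 6 had Xist at 7.05 to 12.46 CPM and the Y-linked genes at 147 to 222 CPM, although the labels give all as pools of both sexes.

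Transcripts of tissues outside the heart were high in some libraries. Gh, the pituitary growth hormone gene, stood at 197 and 394 CPM in E10.5 replicates 3 and 4, at 106, 218 and 169 CPM in the E14.5 libraries and at 322 CPM in E16.5 replicate 1, and under 1 CPM in the others. Pomc, a further pituitary hormone gene, stood at 4.51 to 39.3 CPM in the libraries high in Gh and at 0.779 to 1.91 CPM in the others. Afp, of yolk sac and liver, stood at 45.1 CPM in E9.5 replicate 2 and 3.39 CPM in E10.5 replicate 1, and Sftpc, of lung epithelium, at 3.98 CPM in E16.5 replicate 4. Krt5 stood at 3.78 to 5.41 CPM in some libraries of E9.5, E12.5 and E16.5 and at most 0.258 CPM elsewhere. Gh parts the E14.5 libraries from all at E12.5 and most at E16.5. Its bearing on these comparisons was not tested. These genes were chosen after their values were seen.

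The 8 macrophage-type transcripts, high in 13 libraries and low in 5, define the batches. Their median batch coefficient (8.32, log2) is high by construction. The 15 macrophage list genes had 1.22 (SD 0.921). This argues against a rise of macrophages as a whole as large as that of the 8 transcripts. A smaller rise of macrophages stays open. Reads of another library of the series would vary with its share, and the highest sum was 2.02 times the lowest among the 13, which argues against them. Reads passed between libraries handled together are a candidate explanation, since Y-linked transcripts in the 4 Xist-high libraries with the 8 transcripts (3.35 to 4.61 CPM, 1.83 to 2.52% of the 183 CPM of the 6 Xist-low libraries) were at least 15.8 times those of the 1 without (0.212 CPM, 0.116%). This rests on 1 library, the threshold for this ratio was set after the values were seen, and no other explanation was tested.

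Mevalonate enzymes were lower at later stages, with a median of -1.15 from E9.5 to E16.5. With the batch as a term the median was -1.10, and with the trend with GC content and length over 18827 genes removed it was -1.19, which argues against batch and gene composition as the whole cause. A loss of red cells from E10.5 to E12.5 was not excluded: of 3 criteria tried in turn, each after values had been seen, 2 left it open, the primitive erythroid median (0.91, SD 0.983, and -0.0081 within batch 1) and the lowest globin share at E12.5 over the highest at E10.5 (1.02, first set to be over 1 and passed by less than the spread), and the last, the exact permutation p of the globin share times 3 (0.0857), decides nothing, since 0.0286 is the smallest p that 4 against 4 allow and it could not have passed. Of the red cell genes 5 of 10 primitive erythroid genes rose and 0 fell, all 4 adult globin genes rose (median 3.64, SD 0.745, with 2.86 in batch 1 and 3.49 in batch 2) and globin shares were 1.19 ± 0.331% and 3.52 ± 1.47% (0.915 and 1.62% in batch 1, 1.47 and 4.15% in batch 2), which speaks against such a loss, but adult globins also switch on in red cells with stage, so their level does not count cells. From E12.5 to E14.5 the primitive erythroid median was -3.84 and that of adult globin genes -0.081 (SD 1.55, 0 of 4 passed), so a loss of red cells or a change in their kind and the fall of the enzymes cannot be told apart, and a change with stage in the heart cells stays open as well.

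Fibroblast and epicardial genes were higher at E10.5 than at E9.5. A lower heart muscle share would raise other cell types alike. The fibroblast median exceeded the endothelial one by 1.70 (combined SD 1.07, criterion set later). The megakaryocyte (1.38) and early contractile (-0.36) medians go with a lower share. Core sarcomere (-0.19), endothelial (-0.13) and coronary endothelial genes (-0.24) did not pass, and calcium handling genes passed upward (0.050). A lower share stays open. With the batch as a term the fibroblast median was 1.64, which argues against batch as the whole cause. A change of fibroblast and epicardial cells with stage stays open, untested.

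For each comparison, all 35 splits of the libraries into groups of the same sizes were fitted. Chance could be excluded for the gene counts, each with 1 split as large, the real one (at most 1269, 1, 498, 1045 and 7886 genes in other splits). A split that followed the batch gave 1248 genes for E10.5 with E9.5. The real split of E16.5 with E9.5 itself follows the batch, since 2 of 3 libraries at E9.5 and 0 of 4 at E16.5 belong to batch 1. Its rank among the splits does not exclude batch there. With the batch as a term 11791 genes passed. Within batch 2 the mevalonate median was -1.19, but this rests on 1 library at E9.5. The other 4 splits that kept the batch 1 libraries together in the group of 3 gave at most 1 gene. This decides nothing, as both groups mix the stages. For lists the real split alone was the highest for E10.5 with E9.5 (23 against 21) and E14.5 with E12.5 (24 against 21). It was not for E12.5 with E10.5 (20 against 20, 4 splits as large), E16.5 with E14.5 (19 against 20, 2 splits) and E16.5 with E9.5 (25 against 26, 3 splits). The real mevalonate median was largest in size for E12.5 with E10.5 (0.404 against 0.249) and E14.5 with E12.5 (0.439 against 0.351). So it was for E16.5 with E9.5 (1.15 against 1.01). It was not for E10.5 with E9.5 (7 splits, highest 0.062) and E16.5 with E14.5 (19 splits, highest 0.192).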
